A study of Caenorhabditis elegans with 17 samples.

How the data were processed

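RNA was sequenced from day 1 adults, 96 h old and grown at 20 °C, in 17 libraries made from 1 to 5 µg of RNA with a TruSeq stranded mRNA kit, per the labels. The groups were L4440 (5 libraries), ash-2 RNAi (4), hsf-1 RNAi (4) and both clones (4), and all per-library columns could be mapped to a labelled library. The series was analysed without its paper. The authors used cutadapt, HISAT2, StringTie and DESeq2 with genome build WBcel235, per the submitters' processing notes; the tools' versions, and which of them made which column, are not given in the sources used here.

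The FPKM values were made by the authors and deposited as one value per gene and library, fragments per kilobase of transcript per M mapped fragments. The fold change, a ratio of group means, was computed by the authors and deposited in 3 comparison tables. The log2 fold changes deposited by the authors equal the binary logarithm of the ratio of the group mean FPKM values. The p-value and q-value columns were also deposited by the authors, and the significance mark follows a q-value under 0.05 and an absolute log2 fold change of at least 1, with 0 exceptions. The authors' tables were used only for the comparison of calls that closes the report. A sheet that carries gene symbols only was not used here, and read counts were not used here.

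Of 26786 genes in the table, 26780 were matched to the RefSeq gene table of WBcel235, from which gene coordinates were taken, and 99.1% had a transcript length. Counts of fragments were not given, so depth was estimated from low FPKM values times length in genes with 1 transcript. Their most common value within a fixed window was taken as 1 fragment, which gave 16.3 to 19.5 M fragments per library. The window bounds the estimate, so similar depths across libraries were partly fixed in advance. At that depth a gene at an FPKM of 1 rests on few fragments, and low genes vary most. Near-identical genes (msp, histone, pud-1.1 and pud-1.2, nspd, hsp-16, vitellogenin and some collagen genes) share reads, so the value of a single member stands partly for its relatives. The promoter of the transgene is that of unc-54, and reads from untranslated parts of the transgene can count for that gene.

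Before the data were examined, groups, comparisons, tests, 27 gene lists and the first set of alternatives were fixed. Values were taken as log2(FPKM + 0.5), which understates changes of genes at low levels. Genes with an FPKM of at least 1 in at least 4 libraries were tested, 13084 in all. All 17 libraries were fitted together with limma 3.58.1 (lmFit, then eBayes with trend and robust settings) in R 4.3.3. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The contrasts were ash-2 against L4440, hsf-1 against L4440, both clones against ash-2, against hsf-1 and against L4440, and the interaction (both clones minus hsf-1, minus ash-2, plus L4440). p was adjusted by Benjamini-Hochberg over the genes of a contrast and a gene was called at an adjusted p under 0.05; words such as rose, fell, higher and lower for single genes mean called unless a p says otherwise. The SE of a change comes from the same fit. A test of these sizes of groups measures spread between libraries of 1 experiment.

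Gene lists were tested with camera at its preset correlation of 0.01, and again with a correlation estimated from the data, each adjusted over the 27 lists; a list's members were also adjusted over the list alone. The lists cover inducible heat shock proteins, constitutive cytosolic chaperones, mitochondrial and endoplasmic reticulum unfolded protein responses, proteasome, autophagy and lysosome, fatty acid synthesis, lipolysis and fatty acid oxidation, phosphatidylcholine and one-carbon metabolism, vitellogenins, H3K4 methylation machinery, insulin signalling, SKN-1 targets, P450 and UDP-glycosyltransferase genes, innate immunity, cuticle collagens, molting, body wall muscle, intestine, neuron, germline, oocyte, sperm, embryo zygotic, small RNA, ribosomal protein and oxidative phosphorylation genes. They were written from general knowledge of the organism, and 4 members (daf-21, gnmt-1, sodh-1 and trp-3) matched no gene under those names. The levels of the targets ash-2 and hsf-1 were compared with L4440 by an exact two-sided permutation test on FPKM (126 arrangements), adjusted over 6 tests.

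The genes named in the text come from a rule. It gives the targets, then the 6 called genes with the highest and the 6 with the lowest log2 change (3 and 3 for both clones against hsf-1 and against L4440) among those with a gene symbol and a mean FPKM of at least 10 in the higher group. Their FPKM ranges in the groups compared may not overlap, which is not asked of the interaction. Last come up to 4 members of each list with the smallest adjusted p, except for both clones against hsf-1 and against L4440. The text names a selection of the genes this rule gives, and that selection was made after the values were seen.

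The 2 ash-2 contrasts that share no library (against L4440, and both clones against hsf-1) were compared by Pearson and Spearman correlation with a jackknife SE over libraries. That correlation was set against 100 simulated draws of unchanged groups, and counts of genes called in 2 contrasts that share a group were set against contrasts in which the shared group was split. Counts of called genes in each contrast were set against other splits of the same libraries into groups of the same sizes, up to 100 with the real one. So were the correlation, the genes called in opposite directions when hsf-1 RNAi was added, and those called in the same direction with each single clone. Counts of lists were treated so in 4 contrasts: ash-2, hsf-1, both clones against ash-2, and the interaction. Genes called in opposite directions with the single clones were not treated so. The scripts were tested on simulated data with 200 changed genes among 13084. The noise was drawn independently for each gene and library, without the structure that the genes of a library share. The rates that follow hold for such noise and do not describe these libraries. For ash-2 against L4440, 40% of 2-fold and 83% of 4-fold changes were recovered with 13 false calls, and for hsf-1 against L4440 37% and 85% with 4. For both clones it was 36% and 87% with 7 against ash-2, 33% and 82% with 10 against hsf-1 and 36% and 90% with 4 against L4440. For the interaction it was 5% and 67% with 3.

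The alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, a replicate block by title number or by library number, array weights, eBayes without trend and robust settings, a fit of only the groups compared, an estimated list correlation and leaving out each library. After the data were seen, 3 more were added: leaving out the 4 libraries with fewer than 11000 detected genes, removing each library's trend on transcript length (lowess, span 0.4), and the number of detected genes as a covariate. A value that stood apart from its group was found with Dixon's ratio (over 0.829 with 4 libraries, 0.71 with 5). Also after the data were seen, lists of intracellular pathogen response, histone and embryonic patterning genes were added; they are used only in the closing part.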

Results

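Whole-animal messenger RNA of day 1 adult Caenorhabditis elegans was measured in 17 libraries. All animals carried rmIs133, a transgene in which the promoter of the muscle myosin gene unc-54 drives a polyglutamine stretch fused to YFP in body wall muscle. Animals were fed bacteria that make double-stranded RNA, which lowers the matching worm transcript. The groups were the empty feeding vector L4440 (n = 5), ash-2 RNAi (n = 4), hsf-1 RNAi (n = 4) and both together (n = 4). ash-2 encodes a core subunit of the complexes that methylate lysine 4 of histone H3, and hsf-1 encodes the heat shock transcription factor. The parents of the ash-2 and the ash-2 + hsf-1 animals had also been kept on ash-2 RNAi, so every comparison between these groups and the others includes that difference between parents. The labels call the libraries biological replicates. Levels are FPKM, given as mean ± SD over the libraries of a group, and log2 changes carry their standard error (SE).

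The FPKM steps of the lowest genes implied 16.3 to 19.5 M fragments (M, mega) per library, an estimate since the values used are not counts. It was sought within a fixed window, so it is a weak measure of differences in depth between libraries. Libraries differed in how many genes reached an FPKM of at least 1. It was 9401 and 9817 genes in ash-2 replicates 1 and 3, 10591 in ash-2 + hsf-1 replicate 3 and 10745 in hsf-1 replicate 4, against 11170 to 13066 in the other 13 libraries. The first principal component of all tested genes held 52.9% of the variance and ordered the libraries largely by this number, from -72.2 in hsf-1 replicate 3 to 131.2 in ash-2 replicate 1. Leaving these 4 libraries out moved several counts and calls, as given below.

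**Figure D1:**
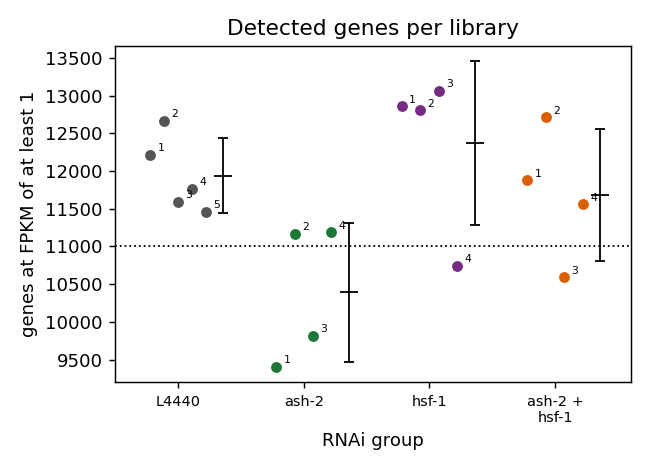
Number of genes at an FPKM of at least 1 (y axis) in each library (points, numbered by replicate) of the 4 RNAi groups (x axis), with bars for mean and SD and a dotted line at 11000 genes. Both ash-2 replicates 1 and 3 (9401 and 9817 genes), hsf-1 replicate 4 (10745) and ash-2 + hsf-1 replicate 3 (10591) lie below the line.

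The target transcripts were examined first. The ash-2 transcript (Y17G7B.2, chromosome II, 11979838 to 11989050, WBcel235) was at 16.39 ± 1.89 FPKM with L4440, 5.46 ± 3.65 with ash-2 RNAi (33.3% of control) and 8.47 ± 3.42 with both RNAi clones (51.7% of control). The hsf-1 transcript (Y53C10A.12, chromosome I, 11953509 to 11961984) was at 29.9 ± 2.92 FPKM with L4440, 12.5 ± 3.55 with hsf-1 RNAi (41.9%) and 9.74 ± 2.60 with both (32.6%). In each of these 4 comparisons all 4 RNAi libraries lay below the lowest of the 5 L4440 libraries, and a two-sided exact permutation test over 126 arrangements gave p = 0.0079, the smallest it can give (adjusted p = 0.0119 over 6 tests). The non-targeted transcript did not differ by the same exact test: hsf-1 was at 30.03 ± 12.7 FPKM with ash-2 RNAi (p = 0.984) and ash-2 at 14.2 ± 5.72 with hsf-1 RNAi (p = 0.595). The equal hsf-1 means came from libraries on both sides of the L4440 range, 26.45 to 33.79: 16.32 and 22.14 in the few-detected ash-2 replicates, and 41.47 and 40.19 in the others. With detected genes as covariate the change was 0.64 (adjusted p = 0.013, limma). Every ash-2 library had fewer detected genes (at most 11189) than every L4440 library (at least 11459), so this adjusted value is an extrapolation. An effect of ash-2 RNAi on hsf-1 stays open. Among the hsf-1 libraries ash-2 was at 16.8 to 17.4 FPKM in replicates 1 to 3 and at 5.57 in replicate 4. Genes changed strongly by ash-2 RNAi did not all place replicate 4 alike. On pud-3 (1.19 FPKM) and clec-67 (16.3 FPKM) it lay with its own group. Its cyp-14A5 level, 4.207 FPKM, lay within the ash-2 range (1.78 to 7.015) and below hsf-1 replicates 1 to 3 (20.5 to 24.02). Its clec-10 level, 11.85 FPKM, lay between the ash-2 libraries (0.9595 to 2.185) and hsf-1 replicates 1 to 3 (31.76 to 38.39). The mean log2 level of the sperm list, relative to L4440, was 0.703 there, against -3.121 to -2.004 with ash-2 RNAi. The untargeted cfp-1 was also low in replicate 4, at 7.049 FPKM against 22.58 to 27.38 in hsf-1 replicates 1 to 3. In the few-detected ash-2 replicates it was at 3.366 and 5.532, against 28.41 and 30.51 in the others. The median of all tested genes, relative to L4440, was -0.56 in hsf-1 replicate 4, though acs-2 was higher there. A fall shared by many genes of this few-detected library can thus be part of the low ash-2 level. Its cause was not tested and stays open. Reads from the feeding construct itself can add to the FPKM of a target, so the levels of targeted transcripts are upper limits of the remaining message. In limma's test, ash-2 was lower with ash-2 RNAi (log2 change -1.74 ± 0.43, adjusted p = 0.00823), while its change with both clones did not pass (-1.01 ± 0.43 against L4440, adjusted p = 0.203). Within the ash-2 group the transcript was at 2.04 and 2.57 FPKM in the few-detected replicates 1 and 3 and at 8.68 and 8.54 in replicates 2 and 4, which lie close to the mean with both clones. The ash-2 level with both clones differed from that with ash-2 RNAi alone by 0.73 ± 0.45, which did not pass the test (adjusted p = 0.301), and by 0.19 without the 4 libraries with few detected genes (adjusted p = 0.56).

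**Figure D2:**
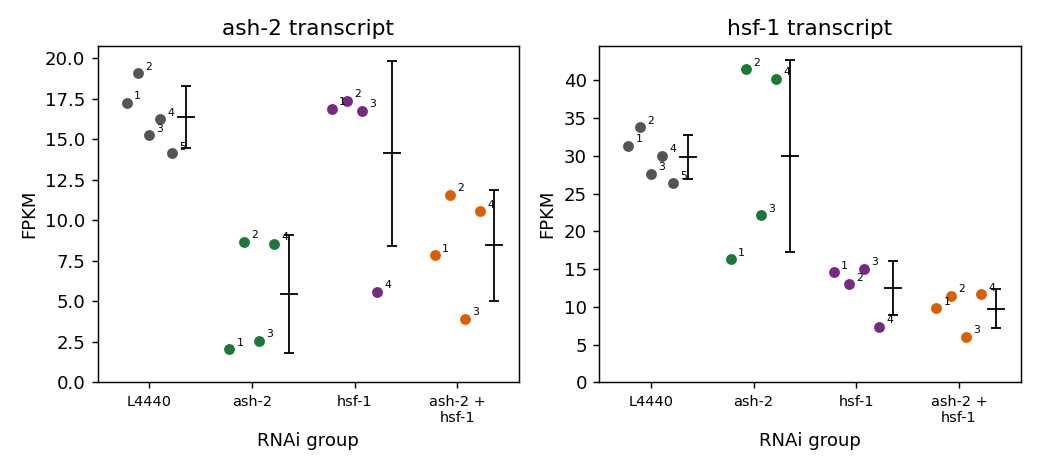
FPKM (y axes) of the ash-2 transcript (left) and the hsf-1 transcript (right) in each library (points, numbered by replicate) of the 4 RNAi groups (x axes), with bars for mean and SD. Every library fed the matching RNAi clone lies below the lowest L4440 library, at 14.1 FPKM for ash-2 and 26.5 FPKM for hsf-1.

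The first comparison asked what ash-2 RNAi changed. Sperm transcripts fell in nearly the whole of the list: 54 of 57 measured members were lower and none higher (55 lower when adjusted over the list alone), with a median log2 change of -2.79. The sperm phosphatase gsp-3 went from 35.95 ± 1.55 FPKM with L4440 to 4.55 ± 1.93 with ash-2 RNAi, the major sperm protein gene msp-77 from 116 ± 4.18 to 18.1 ± 8.39, and the sperm-enriched nspd-2 from 26.6 ± 7.14 to 2.41 ± 1.00. Cuticle collagens fell as well, 74 of 139 lower and 15 higher (82 and 16 over the list alone, median -0.74), among them col-138 from 165.4 ± 35.2 to 29.2 ± 15.8 FPKM and col-97 from 86.03 ± 16.22 to 26.6 ± 5.32. By contrast, 10 of 33 molting and larval cuticle genes rose and 2 fell (11 and 3 over the list alone, median 0.38), including the cuticulin cut-2, from 48.6 ± 4.90 to 205 ± 93.9 FPKM, and the lipocalin-related lpr-3, from 13.4 ± 3.70 to 33.9 ± 4.61. The apical matrix gene noah-2 rose too, from 21.98 ± 2.52 to 51.8 ± 8.15 FPKM.

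With camera, the sperm list had an adjusted p of 1.67e-31, the collagens 0.000246 and the molting list 3.87e-07. With an estimated correlation none of the 3 passed (adjusted p = 0.069, 0.83 and 0.61). Of the other lists tested, the proteasome had 4 of 31 members higher (3 over the list alone, median 0.32, adjusted p = 3.2e-09, and adjusted p = 0.36 with an estimated correlation). Of these, the lid subunit gene rpn-6.1 rose by 0.52 ± 0.13 and the core subunit gene pbs-7 by 0.45 ± 0.12, and both calls were lost without the 4 libraries with few detected genes (adjusted p = 0.084 and 0.25, at 0.37 and 0.24). Oocyte and eggshell genes stood higher as a list (median 0.30, adjusted p = 3.79e-07, and adjusted p = 0.36 with an estimated correlation). Only 1 of its 34 members was called (0 over the list alone), the eggshell proteoglycan gene cpg-2, at 1809 ± 227.6 FPKM against 1346 ± 118.6 (log2 change 0.42 ± 0.15, adjusted p = 0.0497). Embryo zygotic markers had 2 of 11 members higher (3 over the list alone, median 0.52, adjusted p = 0.000152, and adjusted p = 0.37 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.12 with 0 of 43 called (adjusted p = 0.000246, and adjusted p = 0.36 with an estimated correlation). That call was lost without the 4 libraries (adjusted p = 0.641, median 0.01) and under quantile normalization (adjusted p = 0.79).

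Among detoxification, immune and lipid genes, more members were called lower than higher with ash-2 RNAi. The same held over all tested genes, where 78.8% of the calls were lower. Of 108 cytochrome P450 and UDP-glycosyltransferase genes, 28 fell and 2 rose (30 and 3 over the list alone, median -0.83), for example cyp-14A5 from 27.8 ± 6.30 to 4.48 ± 2.64 FPKM and ugt-13 from 26.1 ± 4.64 to 4.34 ± 2.59. This list passed the set test (adjusted p = 0.00952), but not with an estimated correlation (adjusted p = 0.94) and not without the 4 libraries with few detected genes (adjusted p = 0.0965, median -0.20). With detected genes as covariate its median turned to 0.26 (adjusted p = 0.921). Of 44 innate immune genes, 15 fell and 1 rose over all genes and over the list alone (adjusted p = 0.0816 for the list). The antimicrobial peptide gene cnc-4 went from 67.3 ± 19.4 to 12.03 ± 2.01 FPKM, the lysozyme gene ilys-3 from 98.4 ± 26.2 to 18.96 ± 3.599 and the saposin-like spp-5 from 455 ± 60.9 to 172 ± 49.9. Of 29 genes of fatty acid synthesis, desaturation and elongation, 7 fell and 2 rose (8 and 2 over the list alone, adjusted p = 0.799 for the list). The stearoyl-CoA desaturases moved apart. fat-6 fell by 1.00 ± 0.21 on the log2 scale, from 172 ± 40.6 to 87.3 ± 28.4 FPKM, while fat-7 was higher by 1.60 ± 0.28 at a low level, 0.645 ± 0.273 to 2.96 ± 0.800. The fat-6 call was lost without the 4 libraries with few detected genes (adjusted p = 0.088, -0.61). Of 33 genes of lipolysis and fatty acid oxidation, 6 fell and 2 rose over all genes and over the list alone, among them the lipase lipl-5 (-1.30 ± 0.17) and the acyl-CoA dehydrogenase acdh-8 (-2.61 ± 0.28). Here the median was -0.13 while camera's direction was upward (adjusted p = 0.514). In the few-detected ash-2 replicates 1 and 3 the median of all tested genes, relative to L4440, was -0.79 and -0.53, and in replicates 2 and 4 it was 0.07. Single falls of lipid genes are read against that difference.

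Inducible heat shock proteins had 4 of 16 members lower and none higher (7 lower and 1 higher over the list alone, adjusted p = 0.599 for the list). hsp-16.48 was at 2.57 ± 1.56 FPKM against 14.7 ± 3.18, and hsp-16.1 at 4.76 ± 2.62 against 15.2 ± 5.98; the hsp-16.1 call was lost without the 4 libraries (adjusted p = 0.072, -1.04 against -1.64). Of 23 targets of SKN-1 and oxidative stress, 6 fell over all genes and over the list alone (adjusted p = 0.796 for the list). They included the nitrilase nit-1 (-1.93 ± 0.25) and the glutathione transferase gst-4 (-1.90 ± 0.53). The gst-4 call depended on single libraries: it was lost without ash-2 replicate 1 and without ash-2 replicate 3. Its change shrank to -0.69 without the 4 libraries with few detected genes (limma, adjusted p = 0.26). With detected genes as covariate it was -0.58 (adjusted p = 0.22). Among 23 genes of insulin signalling and DAF-16 targets, 2 rose and 2 fell (3 and 4 over the list alone). The mitochondrial superoxide dismutase sod-3 rose by 1.03 ± 0.22, and the lysozyme-like lys-7 fell by 1.19 ± 0.36, a call lost when any one of 7 libraries was left out. Intestine markers had 6 of 23 members lower (13 over the list alone), and germline and meiosis markers had 3 of 40 higher (2 over the list alone, adjusted p = 0.0349, and adjusted p = 0.94 with an estimated correlation). The germline list had a median of -0.13 although camera's direction was upward. The called members included cyb-1, a cyclin B, at 366 ± 48.0 against 260 ± 13.7 FPKM, which was not called without the 4 libraries (adjusted p = 0.10, 0.33 against 0.49). Constitutive cytosolic chaperones and autophagy and lysosome genes each had 1 member higher and 1 lower, of 30 and 34 measured (0 and 0, and 1 and 1, over the list alone), with adjusted p = 0.0349 and 0.0302, and adjusted p = 0.83 and 0.94 with an estimated correlation. Quantile normalization ended both calls (adjusted p = 0.693 for each) and turned the median of the chaperones to -0.02, and the chaperone call was also lost without the 4 libraries (adjusted p = 0.122), though the median was then 0.14 against 0.04. No member of the mitochondrial unfolded protein response (14 measured), small RNA and RNA interference (39), cytosolic ribosomal protein (79) or vitellogenin (6) lists was called, and 1 member each of the endoplasmic reticulum unfolded protein response (21, higher), phosphatidylcholine and one-carbon metabolism (22, higher), body wall muscle (38, lower) and H3K4 methylation machinery (17, lower) lists was. Over the list alone the unfolded protein response and muscle members were not called. Neuron markers had 1 of 49 higher and 1 lower (0 and 1 over the list alone).

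Among genes named by size of change, whether in a list or not, the highest log2 changes were in pud-3 (4.75 ± 0.29), the cuticulin cut-3 (4.17 ± 0.44), the collagens col-165 (3.87 ± 0.56) and col-74 (3.75 ± 0.57), pud-4 (3.35 ± 0.47) and the astacin protease nas-3 (3.22 ± 0.29). pud-3 (F15E11.15, chromosome V, 2324634 to 2325152) went from 1.815 ± 0.567 FPKM to 63.0 ± 21.5. The lowest were in nspd-1 (-4.03 ± 0.55), fip-6 (-4.02 ± 0.60), the C-type lectin clec-10 (-3.82 ± 0.36), nspd-6 (-3.47 ± 0.46), ssq-4 (-3.42 ± 0.29) and gipc-2 (-3.29 ± 0.35). For these 12 genes all adjusted p lay at 0.000122 or lower, and the FPKM ranges of the groups did not overlap. In all, 2570 of 13084 tested genes passed an adjusted p of 0.05, 546 higher and 2024 lower (78.8% lower). The median of all tested genes was -0.32, and it was -0.20 after median-of-ratios scaling and 0.06 after quantile normalization, so single changes are read against that shift. Without the 4 libraries with few detected genes it was 0.07. Under quantile normalization 44.7% of 2951 calls were lower, and the split was also nearly even with each library's trend on transcript length removed (49.8% of 3818). Without the 4 libraries there were 1994 calls, 75.5% of them lower, 1762 of them shared with the 2570.

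**Figure D3:**
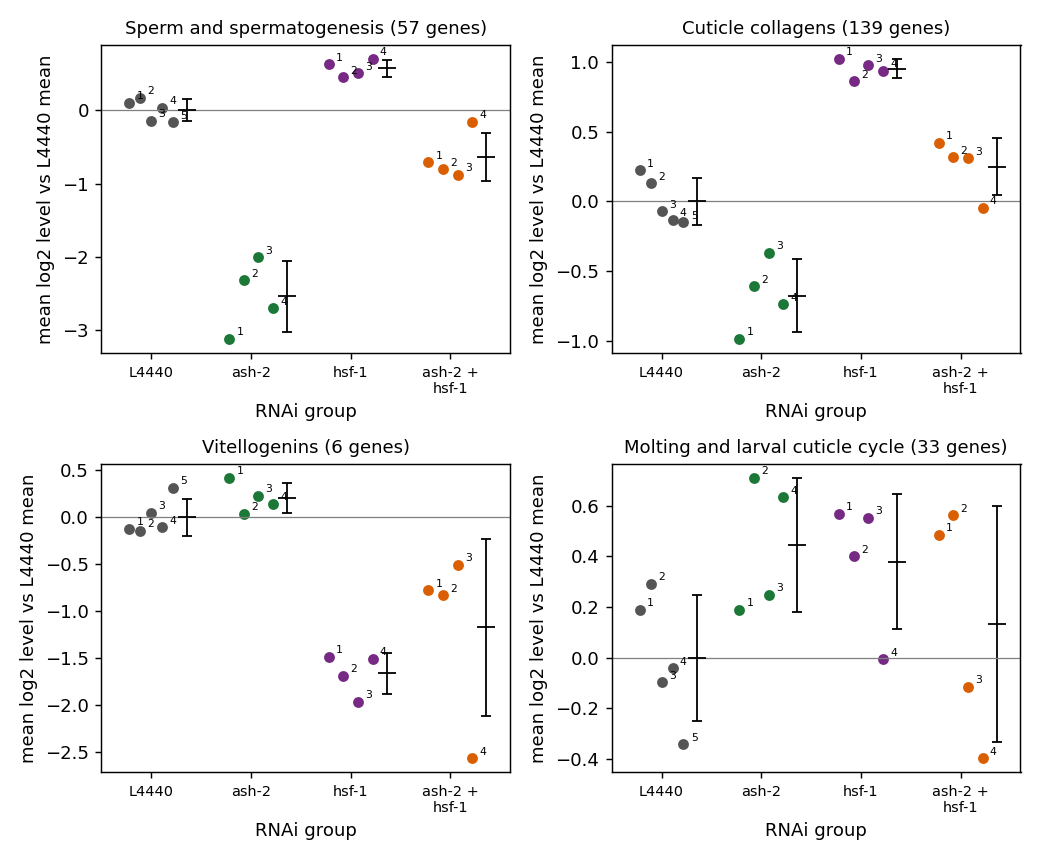
Mean log2 level of 4 gene lists, relative to the L4440 mean (y axes), in each library (points, numbered by replicate) of the 4 RNAi groups (x axes), with bars for mean and SD. The sperm list lies between -3.12 and -2.004 in the ash-2 libraries and between -0.88 and -0.16 in the ash-2 + hsf-1 libraries. The collagen list lies between -0.99 and -0.37 with ash-2 RNAi and between 0.86 and 1.02 with hsf-1 RNAi.

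The second comparison asked what hsf-1 RNAi changed. Cuticle collagens rose: 82 of 139 were higher and 3 lower (97 and 4 over the list alone, median 0.97), with col-104 going from 59.0 ± 7.90 FPKM to 201 ± 30.5, col-97 from 86.03 ± 16.22 to 257 ± 31.3 and col-117 from 240 ± 26.9 to 773 ± 126.8. All 6 measured vitellogenins, the yolk proteins made in the intestine, fell (median -1.66), vit-1 from 421 ± 124.4 to 94.6 ± 21.7 FPKM and vit-4 from 951.3 ± 166 to 273 ± 44.3. Neuron markers had 15 of 49 members higher and none lower (23 over the list alone, median 0.58), among them the neuropeptide gene flp-14 (0.82 ± 0.18) and the neuropeptide processing chaperone sbt-1 (0.73 ± 0.17), both not called under median-of-ratios scaling though as large there (0.87 and 0.78). Constitutive cytosolic chaperones stood lower as a list (median -0.30), with 2 of 30 called (1 over the list alone): the HSP40 gene dnj-13, from 148 ± 14.1 to 82.2 ± 13.5 FPKM, and the immunophilin fkb-6, from 176 ± 7.87 to 111.8 ± 23.8, whose call was lost when any one of 9 libraries was left out. The HSP70 gene hsp-1 was at 1597 ± 587.4 against 2100 ± 180.7 FPKM and did not pass (adjusted p = 0.138), but was called without the 4 libraries with few detected genes (adjusted p = 0.0025).

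In camera's test the adjusted p was 1.71e-29 for collagens, 9.15e-08 for vitellogenins, 5.3e-09 for neuron markers and 0.000121 for chaperones. None held with an estimated correlation (adjusted p = 0.092, 0.25, 0.25 and 0.39). Of the inducible heat shock proteins, the called members were hsp-17 (1.79 ± 0.21, to 71.5 ± 14.99 FPKM from 20.1 ± 2.57) and hsp-25 (0.74 ± 0.16, not called under median-of-ratios scaling, at 0.80), both higher; hsp-16.48 was at 4.89 ± 0.511 against 14.7 ± 3.18 FPKM, which did not pass (adjusted p = 0.0747) except without the 4 libraries with few detected genes (adjusted p = 0.026). Of 16 measured, 2 were higher and 0 lower over all genes, and over the list alone 2 were higher and 2 lower (median -0.61, adjusted p = 0.118 for the list).

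More lipid genes were called lower than higher with hsf-1 RNAi. In the few-detected hsf-1 replicate 4 the median of all tested genes, relative to L4440, was -0.56, against 0.15 to 0.21 in replicates 1 to 3. That library can therefore weigh in the falls given here. Fatty acid synthesis, desaturation and elongation had 5 of 29 lower and none higher (6 lower and 2 higher over the list alone), including the elongase elo-2, from 163.3 ± 17.4 to 84.7 ± 9.84 FPKM, and fat-6, to 76.0 ± 3.31 from 172 ± 40.6. Lipolysis and fatty acid oxidation had 8 of 33 lower and 1 higher over all genes and over the list alone. hacd-1, a hydroxyacyl-CoA dehydrogenase, fell by 1.47 ± 0.20, while the fatty acyl-CoA synthetase acs-2 was the member that rose (2.31 ± 0.31). Phosphatidylcholine and one-carbon metabolism had 5 of 22 lower over both, with the cystathionine gamma-lyase cth-1 at 8.80 ± 2.68 against 20.2 ± 3.74 FPKM. The adjusted p of these 3 lists were 0.00954, 0.000132 and 0.00608, and adjusted p = 0.67, 0.52 and 0.52 with an estimated correlation. Insulin signalling and DAF-16 targets had 4 of 23 lower (4 lower and 1 higher over the list alone, adjusted p = 0.0216, and adjusted p = 0.67 with an estimated correlation), a list call lost under quantile normalization (adjusted p = 0.0802), with the length trend removed (adjusted p = 0.103) and with detected genes as covariate (adjusted p = 0.0963), though the median, -0.16, was then -0.29 to -0.19. Oocyte and eggshell genes had 2 of 34 lower over both (median -0.30, adjusted p = 4.15e-06, and adjusted p = 0.40 with an estimated correlation), including the eggshell gene perm-4 at 642 ± 276.8 against 1116 ± 45.6 FPKM (-0.90, and -0.84 without a call under median-of-ratios scaling). The sperm list was higher as a whole (median 0.68, adjusted p = 4.15e-06, and adjusted p = 0.52 with an estimated correlation), with 1 of 57 members called (0 over the list alone). Molting genes had 9 of 33 higher (10 over the list alone, median 0.37, adjusted p = 0.00954, and adjusted p = 0.70 with an estimated correlation), among them cut-2 (1.196 ± 0.22); the list's call was lost without the 4 libraries (adjusted p = 0.0882), though its median was then 0.47. Germline, embryo zygotic and H3K4 methylation genes stood lower and ribosomal protein genes higher as lists (adjusted p = 0.00273, 0.00223, 0.0244 and 0.000619), and adjusted p = 0.67, 0.52, 0.70 and 0.72 with an estimated correlation. The last 2 calls were lost without the 4 libraries (adjusted p = 0.0773 and 0.797), and the mean level of the H3K4 list was -1.300 in hsf-1 replicate 4 and -0.02 to 0.09 in the others.

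Immune genes went both ways: 13 of 44 rose and 9 fell (13 and 11 over the list alone), with a median of -0.26, a mean of 0.29 and an adjusted p of 0.989 for the list. The innate immune gene dod-19 went from 98.3 ± 11.1 to 480 ± 37.1 FPKM. Intestine markers were split as well, 6 of 23 higher and 7 lower (7 and 8 over the list alone), with the intestinal intermediate filament gene ifb-2 at 295 ± 69.5 against 94.7 ± 6.66 FPKM and the gut cysteine protease cpr-1 at 243 ± 24.1 against 1111 ± 217.3. The double-stranded RNA importer sid-2 was higher (0.82 ± 0.22, adjusted p = 0.0206), a call lost when any one of 5 libraries was left out. It was also lost with a replicate block by title number (limma, adjusted p = 0.061), at 0.77. Of 39 small RNA pathway genes 2 were called, both higher, also over the list alone.

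The highest changes were in the C-type lectins clec-60 (6.51 ± 0.27) and clec-86 (5.39 ± 0.39), eol-1 (4.88 ± 0.58), the small GTPase gene rab-11.2 (4.66 ± 0.34), the aspartyl protease asp-17 (4.61 ± 0.30) and the tetraspanin tsp-2 (4.16 ± 0.29). clec-60 (ZK666.6, chromosome II, 10480043 to 10481874) went from 4.33 ± 1.501 FPKM to 427 ± 63.4. The lowest were in the lysozyme lys-10 (-3.599 ± 0.72), the acyl-CoA dehydrogenase acdh-1 (-2.89 ± 0.32), the lysozyme ilys-2 (-2.62 ± 0.13), tbh-1, which encodes the tyramine beta-hydroxylase that makes octopamine (-2.59 ± 0.28), dod-3 (-2.30 ± 0.36) and col-135 (-2.22 ± 0.42). All 12 had an adjusted p of 0.00314 or lower and group ranges that did not overlap. In all, 1391 genes passed, 1010 higher and 381 lower. Leaving out hsf-1 replicate 3 gave 832 calls, leaving out the 4 libraries with few detected genes, which include hsf-1 replicate 4, gave 2844, and quantile normalization gave 2157 calls, 46.1% of them lower against 27.4%. With the number of detected genes as a covariate 64.5% of 5181 calls were lower, so the direction of the split turned.

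The third comparison set ash-2 + hsf-1 RNAi against ash-2 RNAi, which asked what hsf-1 RNAi changed when ash-2 was also targeted. Sperm transcripts were higher with both clones: 47 of 57 rose and none fell (49 over the list alone, median 2.21), msp-77 to 77.3 ± 25.7 FPKM and gsp-3 to 18.1 ± 2.27, against 116 ± 4.18 and 35.95 ± 1.55 with L4440. Cuticle collagens rose, 79 of 139 higher and 8 lower (88 and 11 over the list alone, median 0.95). col-97, at 87.3 ± 6.40 FPKM, and col-38, at 113 ± 18.7, stood against 86.03 ± 16.22 and 91.5 ± 17.5 with L4440. Constitutive cytosolic chaperones fell, 10 of 30 lower and none higher (12 over the list alone, median -0.35), including the chaperonin subunit cct-2, from 247 ± 19.6 to 162.8 ± 23.6 FPKM, the HSP90 co-chaperone sti-1, from 230 ± 37.4 to 132 ± 11.6, and hsp-1, from 2399 ± 372.4 to 1386 ± 160.7. Under median-of-ratios scaling sti-1 and hsp-1 were not called, though as large (-0.88 and -0.87). The 6 vitellogenins fell (median -1.39), vit-1 from 296 ± 17.98 to 114 ± 40.6 FPKM and vit-5 from 2704 ± 372.8 to 1085 ± 536.7. The list's mean level, relative to L4440, was -2.565 in ash-2 + hsf-1 replicate 4 and -0.83 to -0.50 in replicates 1 to 3, so replicate 4 weighs heavily in this fall. The same library had the lowest chaperone level of its group, -0.762 against -0.35 to -0.14 in the others. Molting genes had 8 of 33 lower and none higher (9 lower and 1 higher over the list alone, median -0.38), noah-2 falling from 51.8 ± 8.15 to 23.6 ± 9.68 FPKM and cut-2 from 205 ± 93.9 to 100 ± 5.67, the latter not called without the 4 libraries (adjusted p = 0.066, -0.46 against -0.93).

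These 5 lists had camera adjusted p of 1.53e-23, 5.72e-12, 5.67e-08, 4.4e-07 and 1.04e-05, in that order, and adjusted p = 0.18, 0.20, 0.18, 0.20 and 0.48 with an estimated correlation. Oocyte and eggshell genes had 4 of 34 lower (0 over the list alone, median -0.30, adjusted p = 1.94e-08, and adjusted p = 0.20 with an estimated correlation), among them the yolk receptor gene rme-2 (-0.77 ± 0.23), a call lost without ash-2 replicate 1 or replicate 3. The rme-2 call was also lost with a replicate block by library number (limma, adjusted p = 0.053), still at -0.77. Phosphatidylcholine and one-carbon genes had 6 of 22 lower (7 over the list alone, adjusted p = 3.93e-06, and adjusted p = 0.20 with an estimated correlation), and lipolysis and fatty acid oxidation genes 6 of 33 lower and 3 higher (7 and 3 over the list alone, adjusted p = 8.69e-05, and adjusted p = 0.42 with an estimated correlation), lipl-5 falling by 1.02 ± 0.18. For fatty acid synthesis, desaturation and elongation the median was 0.06 while camera's direction was downward (adjusted p = 0.0378, and adjusted p = 0.59 with an estimated correlation); 5 of 29 were lower and 2 higher over all genes and over the list alone, and elo-2 fell by 0.71 ± 0.13. The call ended under median-of-ratios scaling (adjusted p = 0.0943, median -0.03) and quantile normalization (adjusted p = 0.246, median -0.14), and also with the length trend removed and with detected genes as covariate. The endoplasmic reticulum unfolded protein response had 3 of 21 members lower (4 over the list alone, adjusted p = 0.00635, and adjusted p = 0.56 with an estimated correlation), including the BiP gene hsp-4 (-0.48 ± 0.13), not called without the 4 libraries (adjusted p = 0.055) or under median-of-ratios scaling, with values of -0.51 and -0.56. Proteasome, oxidative phosphorylation and embryo zygotic genes were also lower as lists (adjusted p = 5.93e-07, 0.000791 and 3.53e-05), and adjusted p = 0.21, 0.23 and 0.21 with an estimated correlation. The oxidative phosphorylation call was lost without the 4 libraries (adjusted p = 0.455), and the proteasome call, with 0 of 31 members called by limma, under quantile normalization (adjusted p = 0.286, median -0.12 against -0.24) and with detected genes as covariate (adjusted p = 0.764). The genes most abundant with L4440 had a median of -0.39, relative to L4440, in ash-2 + hsf-1 replicate 4, against 0.04 to 0.11 in replicates 1 to 3. So replicate 4 can also weigh in the falls of the endoplasmic reticulum and proteasome lists. hsp-17 (1.501 ± 0.23) and sid-2 (1.33 ± 0.23) were higher and the intestinal protease asp-1 was lower (-1.40 ± 0.22).

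The genes with the highest changes were clec-60 (6.596 ± 0.28), eol-1 (5.07 ± 0.61), pals-4 (4.33 ± 0.51), srw-86 (4.24 ± 0.29), the F-box gene fbxa-163 (4.17 ± 0.44) and ddn-1 (4.07 ± 0.66). The lowest were acdh-1 (-2.43 ± 0.34), the gonadal innexin inx-8 (-2.02 ± 0.22), mir-8199 (-1.93 ± 0.43), cpr-1 (-1.91 ± 0.20), the collagen dpy-17 (-1.87 ± 0.40) and pud-1.2 (-1.86 ± 0.31). An mRNA library does not measure a mature microRNA, so the mir-8199 value stands for longer transcripts over that locus. In all, 2061 genes passed, 1569 higher and 492 lower. Lower calls made up 57.7% with quantile normalization and 58.7% with the number of detected genes as a covariate, against 23.9%, and 895 genes passed when only these 8 libraries were fitted.

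Of the 2570 genes called with ash-2 RNAi, 1155 were called in the opposite direction when hsf-1 RNAi was added: 233 of the 546 higher ones (42.7%) and 922 of the 2024 lower ones (45.6%). Among them were gsp-3, msp-77, col-97, noah-2 and cut-2. This count, called the reversal below, also takes in genes that hsf-1 RNAi moved in the opposite direction on its own. For example, col-97 was at 220.2 to 290.2 FPKM in the hsf-1 libraries, 83.25 to 96.82 with both clones and 64.52 to 108.8 with L4440. Cuticle collagens had an interaction median of -0.05, and 14 genes in all passed for the interaction. In simulated data with independent noise the interaction test recovered 5% of 2-fold interactions, so few calls do not show that effects simply add. Sperm genes went otherwise, with an interaction median of 1.51 (camera adjusted p = 1.21e-23, and 0.18 with an estimated correlation). Of 57, 0 passed over all genes and 44 were higher over the list alone. With hsf-1 RNAi alone their median was 0.68. So the count on its own does not show that hsf-1 RNAi undid the ash-2 effect, and the lists differed in this. Both comparisons hold the ash-2 libraries with opposite sign. Independent lists of these sizes would share 20.5 and 242.7. With the ash-2 libraries split 2 and 2, so that the comparisons shared no library, the 6 splits gave 406 to 860 genes in opposite directions (median 599) and 9 to 47 in the same direction. Leaving out ash-2 replicate 1 gave 723 genes. Beside this stands the ash-2 transcript itself, which was at 51.7% of control with both clones and at 33.3% with ash-2 RNAi alone, a difference that did not pass the test and rests on the few-detected ash-2 replicates 1 and 3.

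The same ash-2 contrast was also taken on the hsf-1 RNAi background, in ash-2 + hsf-1 against hsf-1. Sperm genes were lower there too, 30 of 57 and none higher (49 over the list alone, median -1.24), and so were cuticle collagens, 65 of 139 lower and 5 higher (78 and 8 over the list alone, median -0.86). The lists had adjusted p = 2.21e-20 and 7.6e-16, and adjusted p = 0.28 and 0.31 with an estimated correlation. The highest changes were in pud-3 (4.06 ± 0.30), pud-1.1 (3.17 ± 0.31) and pud-1.2 (3.17 ± 0.31), and the lowest in clec-10 (-2.66 ± 0.38), the glutamine synthetase gln-2 (-2.13 ± 0.27) and clec-67 (-2.08 ± 0.24). The ash-2 transcript itself did not pass here (-0.68 ± 0.45, adjusted p = 0.481) except without the 4 libraries with few detected genes (-0.76, adjusted p = 0.011). In all, 1270 genes passed, 168 higher and 1102 lower (86.8%). The count was 780 without hsf-1 replicate 3, 2152 without hsf-1 replicate 4, 2235 without the 4 libraries, and 409 in a fit of these 8 libraries; quantile normalization gave 63.5% lower calls, and with the number of detected genes as a covariate the split turned, with 2949 higher and 1686 lower.

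Across all 13084 tested genes, the log2 changes of ash-2 RNAi on the 2 backgrounds had a Pearson r of 0.648 (jackknife SE over libraries 0.267) and a Spearman rho of 0.506, with 65.3% of genes of the same sign. These comparisons share no library, and genes are not independent replicates. Simulated unchanged groups gave a median r of 0.014, a 95th percentile of 0.589 and a highest value of 0.897. Of the 2570 genes called on the control background, 95.8% had the same sign on the hsf-1 background and 1026 were also called there with that sign. Their median change was -1.27 on the control and -0.78 on the hsf-1 background, with a median ratio of 0.610 for single genes. Genes picked by their call on one background regress towards 0 on another, so this ratio is not a test of a smaller effect.

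**Figure D4:**
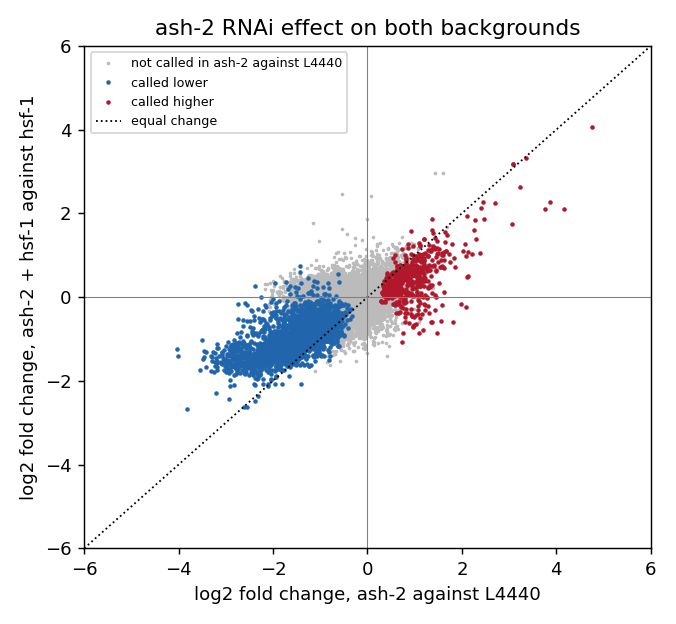
Log2 fold change of each tested gene in ash-2 against L4440 (x axis) and in ash-2 + hsf-1 against hsf-1 (y axis). Coloured points were called higher (546, red) or lower (2024, blue) on the control background, and the dotted line marks equal change. Of the coloured points, 95.8% have the same sign on both axes.

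The interaction tested directly whether the effect of ash-2 RNAi differed with and without hsf-1 RNAi. Among its named genes were several of the cuticle: the collagen sqt-3 (-2.42 ± 0.32), cut-2 (-2.13 ± 0.32) and the lipocalin-related lpr-6 (-2.12 ± 0.32) and lpr-3 (-1.93 ± 0.35) had lower values with both clones than the sum of the single effects. sqt-3 was at 120 ± 20.5 FPKM with L4440, 431 ± 121.1 with ash-2 RNAi, 292 ± 36.9 with hsf-1 RNAi and 198 ± 58.7 with both. The long noncoding RNA gene tts-2 (-2.34 ± 0.28) and the cuticle-related bus-5 (-1.63 ± 0.28) went the same way, and the lysozyme ilys-2 went the other way (1.31 ± 0.19). As a list, molting genes had a median of -0.68 with 2 of 33 called (13 over the list alone, adjusted p = 2.38e-17, and adjusted p = 0.25 with an estimated correlation). Cuticle collagens as a list had a median of -0.05 with 1 of 139 called (1 higher and 4 lower over the list alone, adjusted p = 0.00316, and adjusted p = 0.92 with an estimated correlation), lost the call under quantile normalization (adjusted p = 0.133) and turned without the 4 libraries (median 0.03, adjusted p = 0.0253). The sperm list had a median of 1.51 with 0 of 57 called over all genes and 44 over the list alone (adjusted p = 1.21e-23, and adjusted p = 0.18 with an estimated correlation). The molting and sperm lists kept their direction without the 4 libraries with few detected genes (medians -1.05 and 1.75). The sperm genes nspd-2 (1.69 ± 0.40, adjusted p = 0.19) and ssq-4 (1.75 ± 0.43, adjusted p = 0.231) did not pass on their own.

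Over all genes, 14 passed for the interaction, 2 higher and 12 lower, with 833 at an unadjusted p under 0.05. This count rested on every library: leaving out any single one gave 4 to 9 genes, and leaving out the 4 libraries gave 5 genes, 3 of them shared with the 14. Of the genes named, cut-2, tts-2 and ilys-2 were still called without those 4 libraries, and sqt-3, lpr-6, lpr-3 and bus-5 were not (adjusted p = 0.054, 0.065, 0.11 and 0.077), though their values were then -2.16 to -1.51, about as large. Under median-of-ratios scaling the calls of cut-2 and ilys-2 were lost, at -2.27 and 1.16. The call of bus-5 was lost in 17 settings and that of lpr-3 in 18, on leaving out almost any single library. In simulated data with independent noise, 5% of genes given a 2-fold interaction were recovered, and 67% of those given a 4-fold one. Even with such noise most smaller interactions were not detectable with groups of these sizes.

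Animals with both clones were also set against L4440. clec-60 (6.12 ± 0.27), asp-17 (5.01 ± 0.30) and clec-86 (4.84 ± 0.39) had the highest changes, and nspe-7 (-3.34 ± 0.38), the secreted SCP-like gene scl-2 (-3.08 ± 0.24) and ilys-3 (-2.93 ± 0.29) the lowest. Sperm genes were lower, 10 of 57 called (12 over the list alone, median -0.59), and collagens were higher, 18 of 139 with 5 lower (31 and 6 over the list alone, median 0.16). Vitellogenins had 3 of 6 lower (6 over the list alone, median -1.05), with ash-2 + hsf-1 replicate 4 again lowest, and chaperones 4 of 30 lower (6 over the list alone, median -0.35). The adjusted p of these 4 lists were 4.22e-08, 5.49e-05, 0.000183 and 0.000577, and adjusted p = 0.59, 0.82, 0.59 and 0.59 with an estimated correlation. In all, 1188 genes passed, 482 higher and 706 lower, and with array weights the split turned, 3717 higher and 2758 lower.

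Genes called in both single-RNAi comparisons moved more often in opposite directions than in the same one. Of the genes called with ash-2 RNAi and with hsf-1 RNAi, 58 were higher in both and 67 lower in both. This overlap of ash-2 and hsf-1 effects, 125 genes, was 78 without L4440 replicate 4 and 295 under quantile normalization. Meanwhile 277 were lower with ash-2 RNAi and higher with hsf-1 RNAi, and 91 were higher and then lower. Independent lists of these sizes would share 42.1 and 58.9 in the same direction, and 156.2 and 15.9 in opposite directions. Both comparisons share the L4440 libraries, which pushes shared values towards the same sign. With the L4440 libraries split 2 and 3 the 20 splits gave 32 to 44 genes in the same direction (median 40.5) and 74 to 273 in opposite ones (median 129). Detected genes numbered 9401 to 11189 with ash-2 RNAi and 11459 to 12664 with L4440. In hsf-1 replicates 1 to 3 they numbered 12804 to 13066, and 10745 in replicate 4. This difference between libraries could by itself place genes lower with ash-2 RNAi and higher with hsf-1 RNAi, which was not tested. The count in opposite directions was not taken in the other processing settings. The collagens col-97 and col-104 were among the opposite genes, at 26.6 ± 5.32 and 18.5 ± 3.18 FPKM with ash-2 RNAi and 257 ± 31.3 and 201 ± 30.5 with hsf-1 RNAi.

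The authors' deposited tables, which call a gene at a q-value under 0.05 and an absolute log2 fold change of at least 1, mark 3345 genes for ash-2 over L4440 (434 higher, 2911 lower), 1693 for hsf-1 over L4440 (1214 and 479) and 1971 for ash-2 + hsf-1 over ash-2 (1632 and 339). Of those tested here, 1959 of 2536, 967 of 1381 and 1421 of 1695 were called here as well.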

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

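The tests on few-detected libraries, transcript length and oocyte genes and on an infection carried with the bacteria were chosen after the result was seen; the others below were written down before their result. The first pattern weighed was that more genes were lower than higher with ash-2 RNAi. Of the genes called anew without the 4 libraries with few detected genes 75.5% were lower, but 54.7% to 87.6% on leaving out 1 more library, and the median of all genes turned from -0.32 to 0.07. With the trend on transcript length removed 49.8% of calls were lower (46.7% to 60.8%), a correction that also centres each library, and with the number of detected genes as a covariate 1411 of 3710 calls were lower. So neither the few-detected libraries nor a trend with transcript length can be told apart from an effect of lower ash-2 as a source of this split.

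The second pattern was lower sperm transcripts with ash-2 RNAi. The ash-2 libraries with at least 11000 detected genes had list levels of at most -2.32, against -0.17 to 0.17 in the L4440 libraries, which argues against few-detected libraries. Oocyte and eggshell genes had a median of 0.30 against -0.32 for all genes, which argues against a smaller share of germline tissue as the whole source. With the number of detected genes as a covariate that order turned, 0.13 against 0.26 for all genes, while sperm genes stood at -3.01, so a smaller share stays open as a part. That number does not overlap between the ash-2 and L4440 libraries, so these adjusted values are an extrapolation. Embryonic patterning regulators were higher (camera p = 3.23e-07, and p = 0.14 with an estimated correlation), so a later stage, with sperm production over and more embryos held, could account for part of it. Animals whose parents were also on ash-2 RNAi may differ in timing, and that difference was not tested.

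The third pattern was higher intracellular pathogen response transcripts in animals fed hsf-1 RNAi. In the 6 such libraries with at least 11000 detected genes the lowest list level was 1.88, and the 9 libraries without hsf-1 RNAi lay at -0.76 to 0.28, which argues against few-detected libraries. All 8 of the 8 libraries with hsf-1 RNAi lay above the highest of the others, so the rise was not confined to single libraries. The list was written after eol-1 and pals-4 had been named by a rule that asks for ranges that do not overlap. Such a separation was thus favoured in advance, and it is no independent test of an infection of single plates. The lowest of the 8 was at 0.87, and an infection carried with the hsf-1 RNAi bacteria could give the same picture, so it cannot be told apart from an effect of lower hsf-1.

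Other splits of the same libraries were used to ask whether a grouping by chance could give counts as large. For ash-2 against L4440 it was 1 of 100 splits, the real one (2570 genes, the highest other 1589). It was 1 of 100 for hsf-1 against L4440 (1391, 515) and 1 of 100 for both clones against L4440 (1188, 342). No other drawn split reached the real count there, and 1 of 100 is the smallest share this test can give. Other splits mix libraries that differ, which can widen the spread within groups and lower their counts, so chance is not excluded by this alone. The highest other ash-2 split set L4440 replicates 1 to 4 against the other libraries, close to the real grouping. For both clones against ash-2 it was 2 of 35 (2061, 4554) and against hsf-1 2 of 35 (1270, 3440), so chance cannot be excluded by this test. In the first of these the higher split put all 3 libraries with few detected genes on one side, and in the second both of them. The interaction had 3 of 100 (14, 1366), the correlation on 2 backgrounds 5 of 100 (0.648, 0.771), for which chance cannot be excluded, and the reversal 1 of 100 (1155, 0). The draws for the reversal mixed the libraries of L4440, ash-2 and both clones, so they held no ash-2 effect to reverse. That result cannot tell a reversal from an opposite effect that hsf-1 RNAi has on its own. The overlap of both single effects had 2 of 100 (125, 1473). For the interaction and the overlap, splits that called many times the real count show that structure among the libraries, and not only the groups, can make such counts. The numbers of gene lists past the threshold were not exceptional: 37 of 100 for ash-2 (11, 16), 22 of 100 for hsf-1 (15, 17), 7 of 35 for both clones against ash-2 (17, 18) and 40 of 100 for the interaction (11, 18), so chance cannot be excluded for them.

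Of 263 groups of values examined, 21 held a library far from the others, and chance alone marks about 1 in 20. In L4440 replicate 5, vit-1 was at 642.1 FPKM (others 343.8 to 382.3), cpr-1 at 736.2 (1122 to 1271), scl-2 at 52.28 (99.75 to 102.3), clec-10 at 15.94 (30.74 to 36.77), nit-1 at 13.04 (18.82 to 20.37) and bus-5 at 6.485 (9.451 to 10.65). In L4440 replicate 1 clec-86 was at 0.8493 (1.338 to 1.481). In ash-2 replicate 1, col-165 was at 99.78 (60.59 to 63.62) and dpy-17 at 492.5 (355.5 to 367.4); nit-1 was at 5.47 in replicate 2 (3.928 to 4.155) and hsp-4 at 212.1 in replicate 3 (193.4 to 196.4). In hsf-1 replicate 4, the ash-2 transcript was at 5.574 (16.77 to 17.37), hsp-17 at 49.11 (77.42 to 80.87) and acs-2 at 109.4 (38.62 to 43.01), and 10745 genes were detected (12804 to 13066); in replicate 2 cpr-1 was at 207.1 (251.4 to 259.1). With both clones, replicate 3 had col-97 at 96.82 (83.25 to 85.46), col-38 at 140.6 (102 to 105.3) and ilys-2 at 49.23 (43.66 to 44.61), and replicate 4 had gsp-3 at 21.52 (16.61 to 17.25) and lpr-6 at 9.318 (12.55 to 12.97).

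The ash-2 effect differed between animals with and without hsf-1 RNAi in 7 named genes: ilys-2 (1.31), sqt-3 (-2.42), tts-2 (-2.34), cut-2 (-2.13), lpr-6 (-2.12), lpr-3 (-1.93) and bus-5 (-1.63). Of these calls only that of tts-2 held in every setting in which named genes were checked. The calls of cut-2 and ilys-2 were lost under median-of-ratios scaling. Those of sqt-3, lpr-6, lpr-3 and bus-5 were lost without the 4 libraries with few detected genes (though then at -2.16 to -1.51). The call of bus-5 was also lost in 17 and that of lpr-3 in 18 settings fixed in advance.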

How the results depend on the processing

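The 3 alternatives on few-detected libraries, transcript length and detected genes were chosen after the result was seen. Counts kept within 1.5 times in 29 of 31 settings for ash-2 against L4440 and 25 of 31 for hsf-1 against L4440. For both clones against ash-2, hsf-1 and L4440 it was 27, 24 and 27 of 31. It was 25 of 30 for the reversal and 24 of 30 for the overlap, but only 4 of 30 for the interaction. The target tests kept their outcome in all 19. The correlation on 2 backgrounds was judged by another rule, a wide band of 1 jackknife SE (0.267) around 0.648, and stayed within it in 30 of 30. Named genes were not checked without filter, with a mean FPKM of at least 5 or with array weights. Nor were they checked with eBayes without trend and robust settings or in fits of only the groups compared. In the other planned settings 105 of 126 called results for named genes were always called. The other 21 were lost in at least 1 (14 of them under median-of-ratios scaling or quantile normalization), and none reversed. Without the 4 few-detected libraries 14 were not called. Median-of-ratios scaling ended the calls of rpn-6.1, pbs-7 and cyb-1 (ash-2), hsp-25, flp-14, sbt-1 and perm-4 (hsf-1), and hsp-1, sti-1, hsp-4, rme-2 and cut-2 (both against ash-2). The changes were then about as large. rpn-6.1, pbs-7 and cyb-1 were at 0.66, 0.59 and 0.62 against 0.52, 0.45 and 0.49. rme-2 and cut-2 were at -0.86 and -1.02 against -0.77 and -0.93, and perm-4 at -0.84 against -0.90. Depth limits genes near an FPKM of 1 most. Where no cause is given below, the cause was not tested.

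With an estimated correlation 0 lists passed in each of the 4 contrasts with lists counted. A mean FPKM of at least 5 tests fewer genes and gave 996, 778, 953, 511 and 565 calls (ash-2, hsf-1, and both clones against ash-2, hsf-1 and L4440), a reversal of the ash-2 effect by hsf-1 RNAi in 512 genes and an overlap of 81. Quantile normalization gave 2157 for hsf-1, 1792 for both against L4440, an overlap of 295, and 11 and 4 lists (both against ash-2, interaction). Array weights gave 5730, 3812, 7414 and 6475 (hsf-1, both against ash-2, hsf-1 and L4440), a reversal of 2009 and an overlap of 377. Fits of only the groups compared, with fewer libraries, gave 895 and 409 (both against ash-2 and hsf-1). Without the 4 libraries it was 2844 for hsf-1, 2235 for both against hsf-1 and 7 lists for the interaction. With the length trend removed the overlap was 225. The lists for fatty acid synthesis and phosphatidylcholine in hsf-1 against L4440 lost their call with the length trend removed (adjusted p = 0.0647 and 0.11) and with the covariate (0.0608 and 0.118), though their medians, -0.16 and -0.34, were then -0.13 and -0.29, and -0.33 and -0.39. The covariate ended the calls of proteasome and oocyte genes in ash-2 against L4440 (0.628 and 0.99, medians 0.21 and 0.13) and in both against ash-2 (0.764 and 0.393, medians -0.17 and -0.31). Quantile normalization ended those of germline genes in ash-2 against L4440 (0.79, median 0.06) and of the endoplasmic reticulum unfolded protein response in both against ash-2 (0.382, median -0.14). With detected genes as covariate it was 5181, 3548, 4635 and 2449 (hsf-1, both against ash-2, hsf-1 and L4440), a reversal of 2004, an overlap of 303 and 5 lists for the interaction; the hsf-1 transcript in ash-2 against L4440 turned from -0.09 to 0.64 (adjusted p = 0.013, limma), the ash-2 transcript in hsf-1 against L4440 went from -0.32 to -0.64 (adjusted p = 0.011), and in ash-2 against L4440 its call was lost (-0.58, adjusted p = 0.06). The interaction had 9 genes with a pseudocount of 0.1, 8 without filter, 28 with median-of-ratios scaling, 78 with quantile normalization, 752 with array weights, 5 without the 4 libraries, 70 without length trend and 196 with the covariate.

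A replicate block by title number gave 7 interaction genes and changed no other count by over 1.5 times; a replicate block by library number gave 4110 for ash-2 and a reversal of 1921. Libraries of the same title number correlated at -0.69 to 0.69 (median 0.23), over 0.1 in 14 of 24 pairs, and 9 of 17 libraries had their best partner under their number. By library number it was -0.5 to 0.69 (median 0.36, against -0.089 for other pairs), 14 of 22 pairs and 10 of 17 libraries. Not every pair lay over 0.1, so no pairing was used; libraries of the same library number were still more alike than others.

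Leaving out single libraries gave 1799 to 3198 calls for ash-2, 832 (hsf-1 replicate 3) to 1871 for hsf-1, 1408 to 2683, 780 (hsf-1 replicate 3) to 2152 (hsf-1 replicate 4) and 848 to 1532 for both against ash-2, hsf-1 and L4440, 4 to 9 for the interaction, correlations of 0.474 to 0.742, a reversal of 723 (ash-2 replicate 1) to 1552 and an overlap of 78 (L4440 replicate 4) to 178. Lists numbered 9 to 14, 13 to 16, 15 to 18 and, for the interaction, 5 to 13, with 7 without ash-2 replicate 3 or double replicate 2 and 5 without hsf-1 replicate 4. The adjusted p of the exact test of the targeted transcripts was 0.0159 to 0.0429.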

Other observations

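The lists of intracellular pathogen response and histone genes were chosen after the result was seen, and the list of embryonic patterning regulators was written before its own result. Genes of the intracellular pathogen response, which C. elegans turns on against microsporidia and viruses, rose wherever hsf-1 RNAi was fed. Of 36 measured, 29 were higher in hsf-1 against L4440 (median 2.11, camera p = 4.2e-27, and p = 0.03 with an estimated correlation), 35 in both clones against ash-2 (median 2.39, p = 2.85e-21 and 0.052) and 26 in both clones against L4440 (median 1.98, p = 1.91e-35 and 0.015), with 0 lower in each. ash-2 RNAi lowered 4 and raised 0. The genes eol-1 and pals-4 lie in this response, and eol-1 went from 1.144 FPKM with L4440 to 63.38 with hsf-1 RNAi. Because the list was written with these genes in view, its p is descriptive.

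As a list, histone genes stood higher wherever ash-2 RNAi was fed, though most members were not called. Of 66 measured, 24 were higher and 1 lower in ash-2 against L4440 (median 0.59, camera p = 8.35e-21, and p = 0.027 with an estimated correlation), 14 and 1 in both clones against hsf-1 (median 0.66, p = 4.24e-19 and 0.033) and 20 and 1 in both clones against L4440 (median 0.61, p = 5.75e-24 and 0.018). With hsf-1 RNAi alone 13 were higher and 2 lower (median 0.09), and the list as a whole did not pass camera's test. Because the list was chosen after the result was seen, its p is descriptive. Many histone messages lack a poly(A) tail, so an mRNA library measures only part of them.

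Embryonic patterning regulators had 5 of 32 members higher and 0 lower with ash-2 RNAi (median 0.33). With hsf-1 RNAi 1 was higher and 7 lower (median -0.485, p = 0.000106, and p = 0.25 with an estimated correlation).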
